A study of Zea mays with 18 samples.

How the data were processed

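Messenger RNA from immature maize (Zea mays) endosperm, collected 14 days after pollination, was compared between wild type and the opaque2 (o2) mutant on 2-colour cDNA arrays. The o2 gene encodes a bZIP transcription factor of the endosperm, and its mutants have soft, opaque kernels. Per the labels, there were 3 comparisons: the inbred line B46, the inbred line M14, and pools of 8 lines (mixed). Each comparison held 3 independent sample pairs, and each pair was hybridised to 2 arrays with the dyes exchanged, giving 18 arrays. The 2 arrays of a dye swap hold the same pair of RNA samples and were counted as 1 replicate, so n = 3 per comparison and 9 in all.

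Per the labels, spot and background intensities were read from the array images with ImaGene 4.1. The background correction, floor, normalization and software behind the deposited values are not given in the sources used here. The deposited value table holds 1 signed log ratio per array and row, between -9.70 and 11.5. It has 16560 rows, of which 14932 have values, and each clone stands on 2 neighbouring rows with identical values, which leaves 7466 clones with no missing value. The mean of each deposited column was 0, and the median lay between -0.22 and 0.11. The base of the deposited log ratio is not stated; base 2 and the natural log are both possible from the range, so changes are given in log units and a few as folds under each base. On each array, 1 value was shared by between 33 and 202 clones, and its origin is not stated. A floor in both channels would be one source, but on the M14 replicate 1 array with wild type on Cy5 the shared value was 3.95, against a median of 0.11. Scanner intensities were not used here, so no background check or loess fit was made, and the number of arrays limits the precision.

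The direction of the deposited ratio is likely, not settled. The design text names each comparison with wild type first, and the values were therefore read as wild type over o2 on every array, already turned for the dye. The genes z1C1_12 (a 22-kDa zein) and pdk1 (pyruvate orthophosphate dikinase), both textbook targets of o2, were also looked at in setting this reading and had the same sign on both arrays of every pair. Other values leave the question open. The 2 arrays of each dye swap correlated below 0 over all clones in all 9 replicates (r between -0.35 and -0.018). Among the arrays with wild type on Cy5, M14 replicate 1 and mixed replicate 1 correlated at r = -0.34. In the 6 replicates of B46 and M14, 1004 clones kept 1 sign under the reading used and 1280 when the values were turned by the labelled dyes, against 233 by chance. Over all 9 replicates these counts were 599 and 20, against 29 by chance. If the table held Cy5 over Cy3, the o2 effect would cancel in the mean of a dye swap and any dye effect would stay. A dye effect shared by all arrays would also keep 1 sign, so the 599 clones do not tell it from an o2 effect. The counts of calls and of unadjusted p, and the main values of o2 and its targets, are therefore also given with the values turned by the labelled dyes, an alternative chosen after seeing the data.

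Each array was centred on its median, multiplied by -1 to give o2 over wild type, and averaged with its dye-swap partner. Clones were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a mean for each comparison, no covariates, all 9 replicates sharing the estimate of the spread). The prior degrees of freedom were 1.51, beside 6 residual ones. Contrasts were each comparison against 0, their average, and the 3 differences between comparisons. A clone was called at a Benjamini-Hochberg adjusted p under 0.05 over the 7466 clones. "Higher" and "lower" stand for o2 over wild type under the likely direction.

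Gene names came from an old platform annotation that named 489 clones (6.5%) with 370 genes; 94 of these genes had more than 1 clone. No clone named several genes, and the other 6977 clones are unnamed here. Symbols were updated by gene identifier through a gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, which matched 360 genes and left 10 with their platform symbol. No coordinates are printed, because the array names no build. For gene-level tests the clones of a gene were averaged and fitted together with the unnamed clones (7347 features).

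Of 20 gene lists fixed before the data were examined, 2 (storage regulators other than o2, and lipid synthesis) had no named member. The list patterns were written for gene descriptions, but only symbols were at hand, so members were assigned by hand from symbols after the table was seen. By then the values of o2, pdk1, wx1, sh1, dzs18, z1C1_12, gpc3, gpc4 and Asn1 had been seen. The 13 lists with at least 3 genes were tested with camera at its preset correlation of 0.01, with an estimated correlation and fry as alternatives, and adjusted over these lists within each contrast. The rule for named genes, also fixed beforehand, took o2 and its known targets, up to 8 named clones per direction that passed the test with 1 sign in every replicate, using 1 clone per gene, and up to 4 members of each list. Applying the second part to the average of the 3 comparisons was an extension chosen after its counts were seen. There the requirement of 1 sign in all 9 replicates was at first left out by mistake and was restored after the values had been seen, which brought in lpa1 and hda110.

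The scripts were tested on simulated replicates with the spreads of the real clones and replicates, with 200 of 7466 clones changed. At a true change of 1 log unit, 58% of changed clones were recovered in B46, 56% in M14, 56% in the mixed lines and 75% in the average. At 2 log units these shares were 79%, 81%, 81% and 96%. False calls were 17 of 154 calls in B46, 6 of 143 in M14, 1 of 138 in the mixed lines and 4 of 175 in the average. The simulated replicates differed in spread as the real ones did, and the false share in B46 was above 5%.

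Alternatives fixed beforehand were no centring, scaling to the same median absolute deviation, quantile normalization, 18 arrays with the pair as a random block and a dye term, removal of clones at the shared value or of those least repeatable between dye-swap arrays, eBayes with trend and robust options, no moderation, only a comparison's own replicates, replicate number as a block, each replicate left out in turn, and stricter thresholds. Alternatives added after seeing the data were turning by the labelled dyes, weights per replicate, leaving out replicate 3 of M14 and of the mixed lines, and a turned dye term.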

Results

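Transcript abundance in o2 and wild-type endosperm was compared on 18 arrays in 3 genetic settings. B46 and M14 are maize inbred lines, and the mixed samples pooled 8 lines, B46 and M14 among them. Each setting had 3 replicates, each the mean of a dye swap of 2 arrays. The arrays measured 7466 clones, of which 489 carried a gene name. The spread of replicate values over all clones, as median absolute deviation, was between 0.30 and 0.43 log units in 7 replicates and 0.19 in M14 replicate 3 and mixed replicate 3.

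The gene at the centre of the design was measured by 1 clone. Transcript of o2 (LOC542375) was lower in o2 than in wild-type endosperm in 9 of 9 replicates, with means of -0.67 ± 0.15 log units in B46, -0.37 ± 0.18 in M14 and -0.23 ± 0.29 in the mixed lines (SD, n = 3 each). The fall in B46 passed the test (limma adjusted p = 0.0301), as did the average of -0.42 ± 0.074 (SE, adjusted p = 0.0149), while M14 (0.338) and the mixed lines (0.63) did not. The call in B46 ended without each of its replicates in turn (0.168, 0.114 and 0.0817), without M14 replicate 3 (0.0512), mixed replicate 1 (0.0536) or mixed replicate 3 (0.0519), and on the B46 replicates alone (0.218), and with the trend and robust options both calls ended (0.0902 and 0.056), as they did with replicate 3 of both M14 and the mixed lines left out (0.0944 and 0.0802). These signs and sizes rest on the likely direction of the deposited ratio. If the table held Cy5 over Cy3, the o2 effect would cancel in the mean of a dye swap. The values and calls given here would then hold a dye effect instead. Turned by the labelled dyes, o2 was lower in 6 of 9 replicates with an average of -0.084. The genes z1C1_12 and pdk1 helped to set that direction, so their own sign, size and adjusted p are not independent evidence.

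The comparison in B46 asked which transcripts differ between o2 and wild type in this line. The 22-kDa zein gene z1C1_12, which encodes a storage protein, fell by 2.89 ± 1.26 log units (SD, n = 3, limma adjusted p = 0.0371), which is 7.39-fold lower on base 2 and 17.9-fold on the natural log. Without B46 replicate 2 the fall was 3.61 log units (12.2-fold or 37.0-fold), and with the arrays scaled to the same spread 2.42 (5.34-fold or 11.2-fold). The gene pdk1 fell by 1.68 ± 0.12 (adjusted p = 0.00973), 3.20-fold or 5.36-fold. Lower values were also called for LOC541999 (-1.54 ± 0.29), les22 (-1.23 ± 0.23), which encodes an enzyme of porphyrin synthesis, Asn1 (-0.85 ± 0.18), the chaperonin gene CPNA (-0.81 ± 0.08), and 1 clone each of LOC542547 (-0.99) and AR6 (-0.79). The other clone of LOC542547 stood at -0.0040. Higher values were called for gpc4 (0.93 ± 0.26), GPC1 (0.66 ± 0.09) and 1 clone of gpc3 (0.82), genes of cytosolic glyceraldehyde-3-phosphate dehydrogenase (GAPDH). Higher too were the annexin gene Ann6 (0.60 ± 0.11), the glutathione transferase gene gst30 (0.57 ± 0.15), HMG I/Y-2 (0.53 ± 0.15), which encodes a DNA-binding chromatin protein, and the thioredoxin gene trh2 (0.43 ± 0.06).

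In all, 341 of 7466 clones were called in B46, 68 higher and 273 lower, with a median size of 0.63 log units among the higher and 1.04 among the lower; 21 of the 341 had a gene name. This count hung on the replicates of B46. It was 1 without replicate 1, 205 without replicate 2 and 7 without replicate 3, and 223 and 222 without mixed replicate 2 or 3. Of the 16 called genes in B46 that come from the naming rule or the lists fixed beforehand, 0 passed without replicate 1, 6 without replicate 2 and 4 without replicate 3. Fitted on the B46 replicates alone 0 clones were called, and with the values turned by the labelled dyes 5, of which 4 were higher and 1 was lower. There z1C1_12 stood at -0.39, pdk1 at -0.47, les22 stood at 0.011, CPNA at 0.12, gpc4 at -0.018, GPC1 at -0.074 and gst30 at -0.21.

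**Figure D1:**
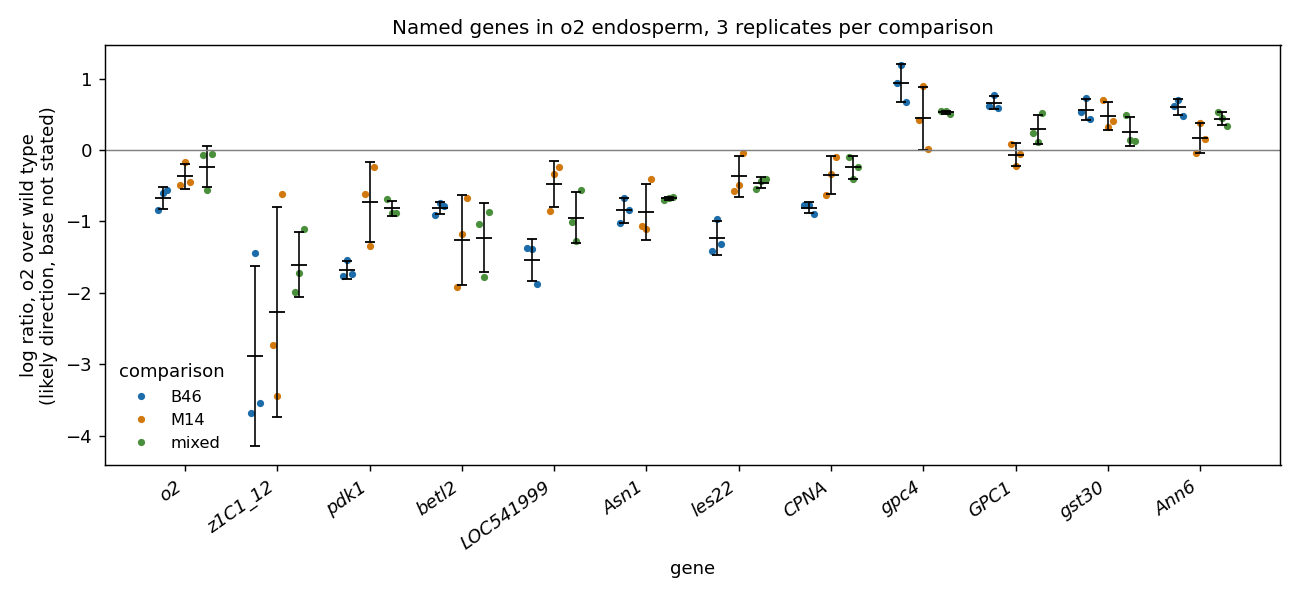
Log ratio of o2 over wild type (vertical axis, log units of unstated base, likely direction) for 12 named genes, with 3 replicates per comparison as points and the mean with SD as black marks; blue is B46, orange M14 and green the mixed lines. The zein gene z1C1_12 lies lowest, with means of -2.89, -2.26 and -1.60, and gpc4 lies above 0 in every replicate.

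Among the gene lists in B46, the 10 glycolysis and fermentation genes stood higher than other genes (median 0.23 log units, 9 of 10 above 0, camera adjusted p = 0.00324; adjusted p = 0.318 with an estimated correlation). Of these, 2 were called higher over all genes, GPC1 and gpc4. Adjusted over the list alone, 5 were higher and 1 was lower. Without the 3 GAPDH genes, the other 7 had a median of 0.16 and did not pass (camera adjusted p = 0.217). The pyruvate decarboxylase gene pdc3 had 1.05 ± 0.57 (SD, n = 3) and the fructokinase gene frk1 0.29 ± 0.02, neither past the test over all genes. The 18 cell cycle and cytoskeleton genes had a median of 0.18 with 15 above 0 (camera adjusted p = 0.0304; 0.318 with an estimated correlation), and none was called. Their largest values were pcna1 at 0.80 ± 0.50, tua6 at 0.59 ± 0.17 and TUA1 at 0.54 ± 0.19. The 9 translation factor genes were all above 0 (median 0.25, camera adjusted p = 0.0484; 0.318 with an estimated correlation), and none was called; eIF3A had 0.78 ± 0.27 and elfa3 0.34 ± 0.25. The call of both lists ended without B46 replicate 1 (camera adjusted p = 0.0645 and 0.112) and without replicate 2 (0.0774 and 0.288), and that of the translation factors also without M14 replicate 1 (0.0644), mixed replicate 2 (0.0578) or mixed replicate 3 (0.0525). Both calls also ended with fry and with all 18 arrays in the fit. Turned by the labelled dyes, neither list passed. The cell cycle list then had a median of 0.094 (camera adjusted p = 0.543) and the translation factors -0.0068 (0.859).

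The other 10 tested lists did not pass in B46. Of 10 starch synthesis genes, 1 was called, iso3 of the debranching enzymes at -0.69 ± 0.28 (SD, n = 3; limma adjusted p = 0.0369), while wx1 stood at 0.31 ± 0.27, ae1 at 0.30 ± 0.21 and zpu1 at -0.52 ± 0.40. The starch list had a median of 0.047 and a mean of -0.039 (camera adjusted p = 0.907). Of 6 heat shock and chaperonin genes CPNA was called, and hsp22 stood at -0.97 ± 0.16 (list median -0.0091, camera adjusted p = 0.638). Of 17 defence and stress genes gst30 was called; the list median was -0.040, its mean 0.0094, and the test pointed up (adjusted p = 0.907). No gene was called among 11 genes of folding in the endoplasmic reticulum (median 0.037, mean -0.093), where PDIL1-1 stood at -0.88 ± 0.52 and bip1 at 0.30 ± 0.14. None was called among 8 amino acid metabolism genes (median 0.012; HMT-3 0.96 ± 0.70, cgs1 0.37 ± 0.27), 12 ribosomal protein genes (median 0.0015; prpl35-1 0.35 ± 0.40), 3 proteolysis genes (median 0.061; LON2 -0.16 ± 0.73) or 4 histone genes (median -0.056; cenH3 -0.78 ± 1.86), each with a camera adjusted p of 0.907. Adjusted over the list alone, the counts were 1 lower for starch, 2 lower for heat shock, 1 higher for defence, 1 higher and 1 lower for folding, 1 higher for amino acid metabolism, 1 lower for the transfer layer, and 0 for the rest. The gene Asn1, called lower in B46 and in the average, was not on the amino acid list. Members of that list were assigned by hand after the value of Asn1 had been seen.

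Marker genes were compared to describe other cell types that the dissected endosperm could hold, among them the basal transfer layer and the aleurone. The 4 genes of the basal transfer layer had a median of -0.034 in B46 (camera adjusted p = 0.907), with betl2 at -0.81 ± 0.09 (SD, n = 3) and betl4 at 0.30 ± 0.38; adjusted over the list alone, betl2 was lower. The 4 genes of green maternal tissue had a median of -0.044 (adjusted p = 0.907; lhcb5 -0.44 ± 0.45). The embryo genes ole1 and dhn2 stood at -0.14 ± 0.02 and 0.02 ± 0.13, and PLTP of the aleurone at -0.09 ± 0.18. These last 2 groups had fewer than 3 measured genes and were not tested as lists. The 18-kDa delta zein gene dzs18 was below 0 in 9 of 9 replicates, with means of -0.74 ± 0.71 in B46, -0.38 ± 0.26 in M14 and -1.08 ± 1.03 in the mixed lines, none of them past the test (limma adjusted p = 0.364, 0.776 and 0.451). With the values turned by the labelled dyes, dzs18 was below 0 in 6 of 9 replicates, with an average of 0.15 against -0.73. Those below 0 were the replicates of B46 and M14, between -1.56 and -0.15. The mixed replicates stood at 4.08, 0.65 and 2.11.

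In M14 no clone passed the test, and 917 had an unadjusted p under 0.05 (limma; 373 by chance; 938 turned by the labelled dyes). The values of the known targets were -2.26 ± 1.47 log units for z1C1_12 and -0.73 ± 0.56 for pdk1 (SD, n = 3; limma adjusted p = 0.281 for both). Among other named genes, betl2 stood at -1.26 ± 0.63, Asn1 at -0.86 ± 0.39, LOC541999 at -0.48 ± 0.33, les22 at -0.37 ± 0.29 and gst30 at 0.47 ± 0.20. The glycolysis and fermentation list had a median of -0.078 (3 of 10 above 0, camera adjusted p = 0.78), with adh2, an alcohol dehydrogenase gene, at -0.74 ± 0.58 and gpc4 at 0.44 ± 0.44. The median was 0.17 for ribosomal proteins, 0.19 for translation factors and 0.10 for histones (adjusted p = 0.541 for each); by fry, which does not compare a list with other genes, the ribosomal proteins passed (adjusted p = 0.0127). It was -0.11 for the transfer layer (0.541; betl2 was lower adjusted over the list alone), -0.041 for starch (0.78), -0.037 for amino acid metabolism (0.801), -0.075 for heat shock (0.627) and -0.023 for proteolysis (0.856). It was 0.028 for defence (0.78), -0.015 for folding (0.981), -0.0090 for the cell cycle (0.856) and -0.0068 for green tissue (0.856); the last 3 had a test that pointed up. The values of M14 replicate 3 were small: without it 44 clones were called, 12 higher and 32 lower, and without replicate 2, 1 clone. With replicate 3 of both M14 and the mixed lines left out, and with weights per replicate, 0 were called. With the arrays scaled to the same spread 40 were called, and with all 18 arrays in the fit 215; turned by the labelled dyes, 0 were called.

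The mixed lines asked for the effect of o2 averaged over backgrounds within the RNA pool. No clone passed the test, and 693 had an unadjusted p under 0.05 (limma; 373 by chance; 499 turned by the labelled dyes). The values were -1.60 ± 0.45 log units for z1C1_12 and -0.82 ± 0.11 for pdk1 (SD, n = 3; limma adjusted p = 0.468 and 0.281). Others were betl2 at -1.23 ± 0.48, LOC541999 at -0.95 ± 0.36, Asn1 at -0.68 ± 0.03, gpc3 at 0.59 ± 0.09, gpc4 at 0.53 ± 0.02 and Ann6 at 0.44 ± 0.09. The glycolysis and fermentation list had a median of 0.095 (7 of 10 above 0, camera adjusted p = 0.0653). The median was 0.12 for translation factors (0.354), 0.057 for the cell cycle (0.743), 0.013 for starch (0.743), 0.069 for amino acid metabolism (0.78) and 0.056 for heat shock (0.843). It was -0.18 for the transfer layer (0.743; betl2 was lower adjusted over the list alone), -0.042 for ribosomal proteins (0.811), -0.0072 for folding (0.843), -0.11 for proteolysis (0.843) and -0.084 for green tissue (0.843). The defence list had a median of -0.042 and a test pointing up (0.843), and the histones a median of 0.023 and a mean of -0.15 (0.843). With the arrays scaled to the same spread 58 clones were called, with all 18 arrays in the fit 193, and 2 without mixed replicate 3; turned by the labelled dyes, 0 were called.

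Averaged over the 3 comparisons (9 replicates), z1C1_12 fell by 2.25 ± 0.34 log units (SE), pdk1 by 1.07 ± 0.11 and betl2, a gene of the basal transfer layer, by 1.10 ± 0.14 (limma adjusted p = 0.00883, 0.00414 and 0.00551). Each was lower in 9 of 9 replicates. With the labelled dyes instead, their averages were -0.084, -0.12 and -0.013, none past the test, with z1C1_12 lower in 5 of 9 replicates and pdk1 in 7 of 9. On base 2 these are 4.76-, 2.11- and 2.14-fold, and on the natural log 9.49-, 2.93- and 2.99-fold; with weights per replicate z1C1_12 stood at -1.80 (3.48-fold or 6.04-fold). LOC541999 (-0.99 ± 0.10), Asn1 (-0.80 ± 0.083) and les22 (-0.69 ± 0.075) were lower in 9 of 9 replicates, as was lpa1 (-0.51 ± 0.065), a gene named for the low phytic acid of its mutants. Of the small heat shock proteins hsp22 (-0.71 ± 0.14) was lower in 8 of 9. Of the GAPDH genes gpc4 (0.63 ± 0.096) was higher in 9 of 9 replicates, and both gpc3 (gene mean 0.56 ± 0.094) and GPC1 (0.30 ± 0.061) passed the test. Higher too were gst30 (0.43 ± 0.067), HMG I/Y-2 (0.33 ± 0.052), Ann6 (0.40 ± 0.058) and the histone deacetylase gene hda110 (0.25 ± 0.053). A clone of LOC542547 (-0.70) was called lower while its other clone stood at 0.072. Single clones of copz1 (0.46), 9-24 (0.45) and rcalm (0.42) were called higher while other clones of these genes stood near or below 0, such as -0.043 for copz1 and -0.60 for 9-24.

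The average called 516 clones, 147 higher and 369 lower, of which 405 had 1 sign in all 9 replicates; 39 of the 516 had a gene name. The count was 327 without M14 replicate 1 (67 higher, 260 lower). It was 312 without mixed replicate 1 (51 and 261) and 298 without mixed replicate 2 (51 and 247), so mostly higher calls were lost in proportion. Without B46 replicate 3 it was 499 (151 and 348). With the values turned by the labelled dyes the count was 0 (496 with an unadjusted limma p under 0.05, against 1605). Few higher calls were left with the trend and robust options (5 higher, 244 lower) or at a 1.5-fold change on base 2 (11 higher, 204 lower). Other fits called more, with 265 higher and 442 lower without the clones least repeatable between dye-swap arrays. With all 18 arrays in the fit, which counts both arrays of a pair, 409 were higher and 527 lower. Of the 21 called genes in the average that come from the naming rule or the lists fixed beforehand, 8 kept an adjusted p under 0.05 in every fit fixed beforehand, namely z1C1_12, pdk1, betl2, LOC541999, Asn1, les22, lpa1 and CPNA (LOC541999 was removed by 1 filter and tested in 18 of the 19 fits). These 8 also passed at 0.01, but lpa1 (-0.51) and CPNA (-0.47) are below a 1.5-fold change on base 2, which leaves 6. On the natural log all 8 are above it. Among the 8, z1C1_12 and pdk1 helped to choose the reading, so their calls are not independent of it. The calls of elfa5, hda110 and rcalm held least often, in 6, 7 and 8 of the 19 fits. Of the 341 clones called in B46, 302 were called in the average in the same direction. The average includes the same B46 replicates, so this overlap is partly built in.

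Over gene lists, no camera test passed in the average. By fry, which does not compare a list with other genes, glycolysis and fermentation and translation factors passed there (adjusted p = 0.0309 for both). Glycolysis and fermentation had a median of 0.067 with 3 genes called higher (4 adjusted over the list alone), and translation factors 0.10 with elfa5 called higher at 0.22 ± 0.051 (SE; 3 adjusted over the list alone); the camera adjusted p was 0.113 for both. The cell cycle list had a median of 0.096 (adjusted p = 0.173). The transfer layer list had 1 gene lower, betl2, with a median of -0.0048 (0.934), and heat shock 2 genes lower, hsp22 and CPNA, with a median of 0.0020 and a mean of -0.11 (0.934). Starch (median -0.015, 1 lower adjusted over the list alone), defence (-0.046, gst30 higher), histones (-0.080), proteolysis (0.015), folding (0.00049), amino acid metabolism (0.020), ribosomal proteins (0.041) and green tissue (-0.045) had adjusted p between 0.934 and 0.966. For starch, defence and histones the test pointed up against a negative median, and for proteolysis and folding down against a positive one.

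The comparisons were also set against each other to ask whether the effect of o2 differed with the background. No clone differed past the test between B46 and M14, B46 and the mixed lines, or M14 and the mixed lines, while 733, 394 and 376 clones had an unadjusted p under 0.05 (limma; 373 by chance). Turned by the labelled dyes, no clone differed either, and 441, 1336 and 1299 had an unadjusted p under 0.05. Without B46 replicate 2, 24 clones differed between B46 and M14 and 17 between B46 and the mixed lines, and without B46 replicate 3 these counts were 2 and 3. With all 18 arrays in the fit they were 105 and 5. The difference of the glycolysis and fermentation list passed between B46 and M14 (median difference 0.40 log units, 9 of 10 genes higher in B46, camera adjusted p = 0.000265; adjusted p = 0.354 with an estimated correlation) and between M14 and the mixed lines (median difference -0.19, adjusted p = 0.0187; 0.475 with an estimated correlation). The second ended without M14 replicate 3 (0.193), mixed replicate 1 (0.0688) or mixed replicate 3 (0.195). The gene GPC1 stood at 0.66 ± 0.09 in B46 and -0.06 ± 0.16 in M14, and adh2 at 0.16 ± 0.08 and -0.74 ± 0.58 (SD, n = 3 each), with no single gene of the list past the test of the difference over all genes and 4 higher in B46 adjusted over the list alone. Between B46 and the mixed lines no list passed. Turned by the labelled dyes, neither difference passed, with medians of -0.084 (camera adjusted p = 0.642) and 0.14 (0.768), and the list in B46 itself had a median of -0.011 (0.859).

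**Figure D2:**
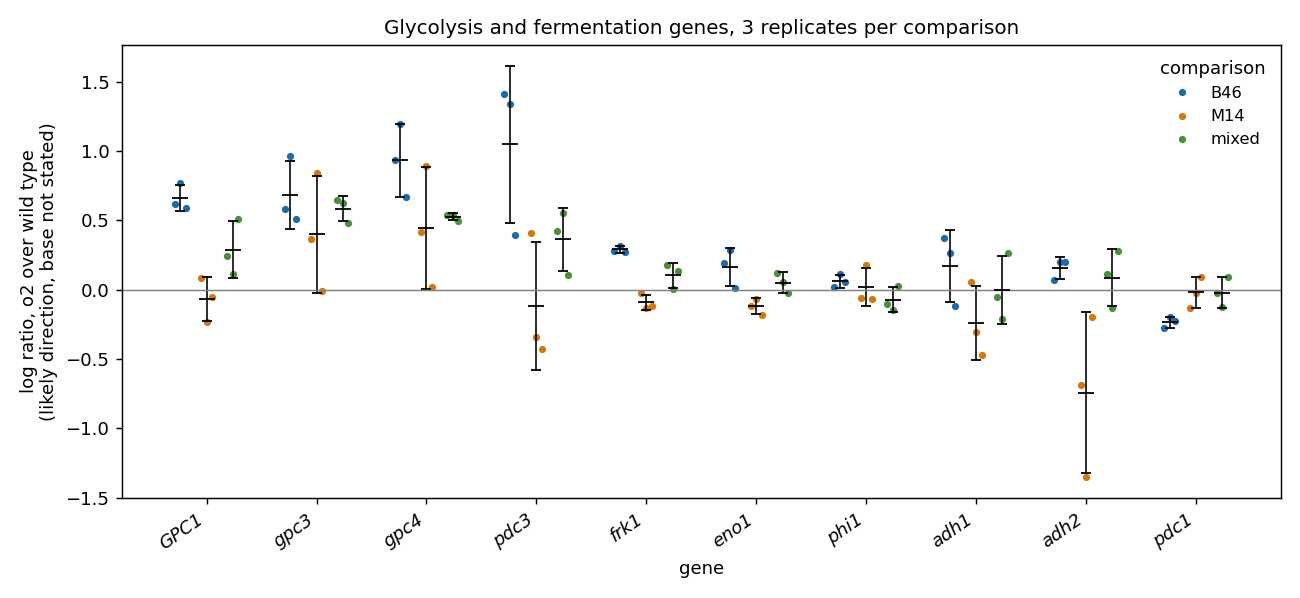
Log ratio of o2 over wild type (vertical axis, log units of unstated base, likely direction) for the 10 glycolysis and fermentation genes, with 3 replicates per comparison as points and the mean with SD as black marks; blue is B46, orange M14 and green the mixed lines. In B46 9 of the 10 means lie above 0, in M14 3 and in the mixed lines 7.

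Across the 7466 clones, which are not independent replicates, the effects of o2 correlated between B46 and M14 (Pearson r = 0.30, Spearman rho = 0.22), B46 and the mixed lines (0.33 and 0.33) and M14 and the mixed lines (0.19 and 0.19). Pearson r, turned by the labelled dyes, was 0.46, -0.50 and -0.52. Without the clones least repeatable between dye-swap arrays it was 0.51, 0.62 and 0.44. Between B46 and M14 it was 0.20 without M14 replicate 1, and between M14 and the mixed lines 0.11 without M14 replicate 2. No clone was called in all 3 comparisons, and with no calls in M14 and the mixed lines the overlap by chance is also 0; with the arrays scaled to the same spread 24 were, all lower, and turned by the labelled dyes 0. Of the 341 clones called in B46, 314 (92.1%) had the same sign in M14 and 329 (96.5%) in the mixed lines, against 58.6% and 65.3% of all clones. When turned by the labelled dyes, 264 of the same clones (77.4%) had the sign of B46 in M14 and 83 (24.3%) in the mixed lines, against 68.1% and 33.2% of all clones. Their median change in the direction of B46 was 0.39 log units in M14 and 0.53 in the mixed lines, against 0.92 in B46, where the choice of clones enlarges the value. Means of the dye-swap arrays correlated above 0 in all 36 pairs of replicates (r between 0.0092 and 0.31). If the table held Cy5 over Cy3, a dye effect shared by the arrays could also give this. The difference of the 2 arrays correlated above 0 among the replicates of B46 and M14 and below 0 between these and mixed replicates 1 and 2.

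**Figure D3:**
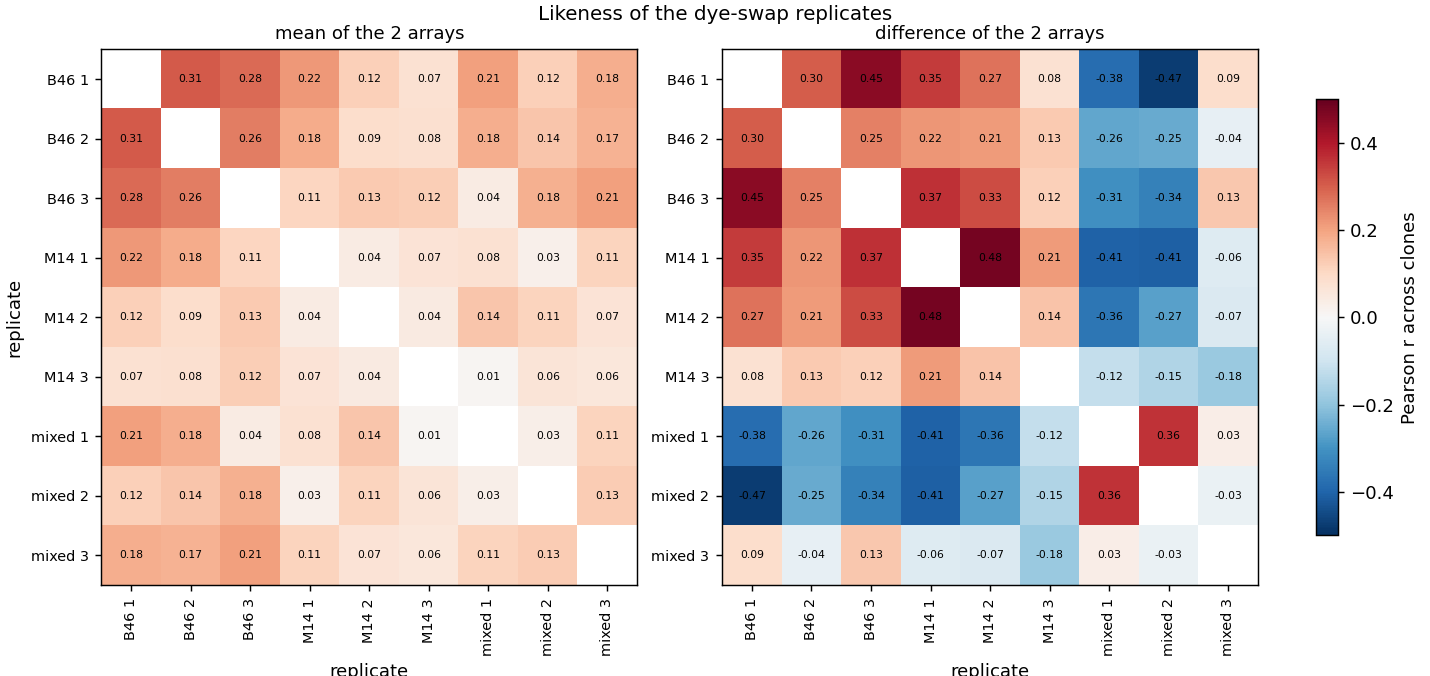
Pearson r across 7466 clones (colour and printed value) between each pair of the 9 replicates, for the mean of the 2 arrays of a dye swap (left) and for their difference turned by the labelled dyes (right). The means have r between 0.0092 and 0.31 throughout, while the differences of mixed replicates 1 and 2 have negative r with every replicate of B46 and M14.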

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

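Chosen after the results were seen were the glycolysis test in B46 alone without its dehydrogenase genes, and the tests of the array differences, of the small effects in M14 replicate 3, and of single replicates behind the glycolysis difference.

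The response of glycolysis and fermentation genes to o2 differed between B46 and M14 by a test of the difference itself (camera adjusted p = 0.000265, median difference 0.40 log units), but not with an estimated correlation (adjusted p = 0.354). Cross-hybridisation among the 3 genes of glyceraldehyde-3-phosphate dehydrogenase could have carried it. Over the 9 replicates gpc3 and gpc4 correlated at r = 0.91, while GPC1 correlated at 0.32 with gpc3 and 0.52 with gpc4. Without these 3 genes the other 7 still differed (camera p = 0.00119, adjusted p = 0.0155, median 0.38), though not with an estimated correlation (adjusted p = 0.488), and at the preset correlation this argues against that source as the whole cause of the difference. In B46 alone the other 7 did not pass (camera adjusted p = 0.217, median 0.16). At the preset correlation a single replicate did not carry the difference between B46 and M14 either. The highest unadjusted camera p with 1 of the 6 replicates left out was 0.000601. Leaving 1 out was not run with an estimated correlation, with which the difference did not pass even with no replicate left out. The adjusted p of the whole list was 0.642 with the values turned by the labelled dyes, so the direction of the ratio, the correlation among the genes and the line itself stay open, the last untested.

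The difference between the 2 arrays of a dye swap ran opposite in mixed replicates 1 and 2 to B46 and M14, which bears on the direction of every value. A possible explanation is an o2 effect that is reversed in the pool, with the deposited ratio being Cy5 over Cy3; mixed replicate 3 had r between -0.18 and 0.13 with B46 and M14, and 1 replicate does not decide it. Another is that the dyes of mixed replicates 1 and 2 were exchanged against their labels: after an exchange all 12 correlations lay between 0.12 and 0.47, but the pattern was found in those values. A technical effect linked to clone position is a further one, and the share of variance between blocks of neighbouring clones was larger for the difference than for the mean in 7 of 9 replicates, short of the 8 set for it. These explanations cannot be told apart with 3 replicates of the pool.

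The o2 effects of M14 replicate 3 were small. Compression of all its log ratios, for instance by normalization, would shrink every clone alike. Over the 341 clones called in B46, its slope on the B46 mean was 0.21 times that of the other M14 replicates (95% bootstrap interval 0.190 to 0.238), against the 0.47 that its spread over all clones gives. The interval covers clones and not replicates: the quotient of both ratios was 0.46 here and 0.58 to 1.39 in the 6 replicates of the other comparisons, whose 95% prediction interval reaches down to 0.39. The B46 replicates among these are part of the B46 mean they were set against, so that interval is only a rough guide. Compression therefore stays open, and neither a fault of that replicate nor a biological explanation was tested.

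The glycolysis and fermentation list also differed between M14 and the mixed lines (camera adjusted p = 0.0187, median difference -0.19), but not with an estimated correlation (adjusted p = 0.475), by fry (0.245), or without M14 replicate 3 (0.193), mixed replicate 1 (0.0688) or mixed replicate 3 (0.195). Among 408 pairs of comparisons over 136 named or listed genes, 16 had all 3 replicates of 1 comparison on 1 side of 0 and all 3 of the other on the opposite side, where chance gives 3.125%. None of the 16 passed limma's test of the difference. Between B46 and M14 the differences were 0.28 log units for eno1 (adjusted p = 0.497), 0.38 for frk1 (0.39), 0.90 for adh2 (0.399), -0.23 for PDIL5-2 (0.531), -0.36 for rpp2 (0.495), -0.33 for rpp2a-3 (0.408), 0.16 for rps27 (0.628) and 0.23 for tua3 (0.557). Between B46 and the mixed lines they were 0.54 for cystatin4 (0.907), 0.35 for RPS10 (0.957) and 0.18 for rps27 (0.908). Between M14 and the mixed lines they were -0.20 for frk1, -0.57 for PDIL5-4, -0.71 for tif1, -0.19 for tua3 and -0.58 for mn1, each with an adjusted p of 0.865.

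Exchanging o2 and wild type within replicates tested whether the counts of called clones exceed those of other groupings. For the average, 1 of 100 exchanges, the real one, gave as many as 516 clones, and the highest other gave 307. Signs that vary at random between replicates therefore rarely give this count. The exchanges cannot tell an o2 effect from a dye effect shared by all arrays, which would also be largest in the real arrangement. Turned by the labelled dyes, 0 clones were called in the average. For B46 the real count of 341 was reached by 1 of 4 exchanges, with 0 as the highest other, and for M14 and for the mixed lines the count of 0 was reached by 4 of 4, with 0 as the highest other. For the differences between comparisons, 10 of 10 splits reached the real count of 0, and the highest others were 1 for B46 and M14, 0 for B46 and the mixed lines and 1 for M14 and the mixed lines. A real count of 0 is reached by every exchange or split by construction, so those tests could decide nothing. For B46, 4 exchanges are too few for a share under 0.05.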

How the results depend on the processing

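Turning by the labelled dyes, weights per replicate, leaving out replicate 3 of both M14 and the mixed lines, and the turned dye term were chosen after seeing the data. Under the alternatives fixed beforehand no called gene or list reversed its direction. Many of these alternatives change the test and not the estimate, so they could not reverse it. Of the calls of genes from the naming rule or the fixed lists, 187 of 303 in B46 and 317 of 398 in the average passed again. The other 116 and 81 did not. In all of these fits 0 of 16 such genes in B46 and 8 of 21 in the average passed at 0.05. With an adjusted p under 0.01 and a 1.5-fold change required as well, 0 and 6 were left on base 2 and 0 and 8 on the natural log. With 1 replicate left out, the count ranged from 1 to 314 in B46, 0 to 44 in M14, 0 to 2 in the mixed lines and 298 to 499 in the average. It ranged from 0 to 24 for B46 against M14 and 0 to 17 for B46 against the mixed lines, and stayed 0 for M14 against the mixed lines and for clones called in all 3 comparisons. The correlation of effects ranged from 0.20 to 0.30 for B46 and M14, 0.28 to 0.33 for B46 and the mixed lines and 0.11 to 0.19 for M14 and the mixed lines. Scaling to the same median absolute deviation called 40 clones in M14, 58 in the mixed lines and 24 in all 3 comparisons. Quantile normalization called 25, 39 and 17, with r of 0.43 for B46 and the mixed lines and 0.25 for M14 and the mixed lines; in B46 it called 20 higher and 217 lower, against 68 and 273. Both give the replicates with small values more weight. Leaving out clones at the shared value gave r of 0.35 for B46 and M14 and 0.40 for B46 and the mixed lines. For M14 and the mixed lines it was 0.25. Without the clones least repeatable between dye-swap arrays, the values in the same order were 0.51, 0.62 and 0.44. Both filters use fewer clones by construction, and the second selects on the values, by the difference of the 2 arrays. Turned by the labelled dyes, that difference is the o2 effect. Why r rose was not tested. All 18 arrays with a dye term called 692 clones in B46, 215 in M14, 193 in the mixed lines and 936 in the average. The same fit called 105 for B46 against M14, 5 for B46 against the mixed lines and 75 in all 3 comparisons. With the dye term turned for mixed replicates 1 and 2 these counts were 731, 255, 197, 975, 104, 6 and 92. The correlation within pairs was estimated at -0.24 and, with the turned term, -0.11, below what independent arrays would have. Both fits take the 2 arrays of a pair as separate observations, with more residual degrees of freedom. A negative correlation also lowers the error given to the mean of a pair. The larger counts are therefore not on the same footing as those from 9 replicates. The trend and robust options called 159 in B46 and 249 in the average (5 higher, 244 lower), and the own replicates alone 0 in B46, with fewer degrees of freedom. An adjusted p under 0.01 left 52 and 231, and a 1.5-fold change on base 2 left 215 in the average (11 higher, 204 lower). With replicate 3 of M14 and of the mixed lines left out, 188 clones were called in B46, 0 in M14 and 289 in the average, with r of 0.28 for B46 and the mixed lines. Weights per replicate gave r of 0.25 for B46 and M14. In B46 the call of the cell cycle list ended with fry (adjusted p = 0.0785), with 18 arrays (0.0829) and with the replicate number as a block (0.0511). That of the translation factors ended with fry (0.0785), 18 arrays (0.0736), the block (0.0998), the trend and robust options (0.068), either filter of clones (0.0529 and 0.155) and the clone with the largest value of each gene (0.0501). The glycolysis call in B46 ended with an estimated correlation (adjusted p = 0.318); fry, which does not compare a list with other genes, gave 0.00945. Between M14 and the mixed lines the call of that list ended with fry (0.245) and without replicate 3 of both (0.353). Where no construction is named, the cause was not tested.

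Turned by the labelled dyes, 5 clones were called in B46 and 0 in the average, and r was 0.46 for B46 and M14, -0.50 for B46 and the mixed lines and -0.52 for M14 and the mixed lines. The direction turned in B46 for les22 (0.011), CPNA (0.12), lpa1 (0.072), gpc4 (-0.018), GPC1 (-0.074) and gst30 (-0.21), and in the average for les22 (0.0069), CPNA (0.042), lpa1 (0.055), AR6 (0.036), gpc3 (-0.00039), trh2 (-0.00073) and rcalm (-0.029). It turned for the medians of glycolysis and fermentation in B46 (-0.011), B46 against M14 (-0.084) and M14 against the mixed lines (0.14), and of translation factors in B46 (-0.0068). None of these passed a test.

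The labels do not say whether the replicate numbers pair samples of different comparisons. Deviations of samples with the same number correlated at r between -0.034 and 0.10. Deviations of samples with unlike numbers were not compared, so pairing stays open. With the replicate number as a block the calls of o2 in B46 and in the average ended (adjusted p = 0.0896 and 0.055), and 185 clones were called in B46 against 341, and the average, with 385, stayed within 1.5 times. Using whichever array of a pair has a value, and only clones with values on all 18 arrays, changed nothing, since no value was missing. Signal over background was not used here, so the limit it sets on weak spots is not known.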

Other observations

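These 4 gene groups and the test of neighbouring clones were chosen after the gene names were seen. Of 9 aquaporin genes, water channels of the membrane, SIP1A fell in B46 (-0.66 ± 0.29 log units, SD, n = 3, limma adjusted p = 0.0499) and in the average (-0.49 ± 0.085, SE, adjusted p = 0.0145), lower in 9 of 9 replicates; it was named after its values were seen. Its call in B46 held in 5 of the 19 other fits fixed beforehand and ended without each B46 replicate in turn. The call in the average held in all 19, but not at 0.01 or with replicate 3 of both M14 and the mixed lines left out (0.061). Turned by the labelled dyes, SIP1A stood at -0.058 and 0.046. The group had a median of 0.090 in B46 (camera adjusted p = 0.879) and -0.019 in the average (0.932). Of 19 genes of chromatin factors, hda110 rose in the average (0.25 ± 0.053, adjusted p = 0.0333), higher in 9 of 9 replicates. Its call held in 7 of the 19 other fits fixed beforehand and ended in 8 of 9 fits with 1 replicate left out (adjusted p up to 0.0998). The chromatin group had a median of 0.17 in B46 (camera adjusted p = 0.879) and -0.015 in the average (0.932). None was called among 5 cellulose synthase genes (median 0.11 in B46, 0.071 in the average) or 6 genes of growth-regulating factors or 14-3-3 proteins (0.028 and -0.0096), with the same adjusted p values. None of the 4 groups passed camera in M14 or the mixed lines, where the lowest adjusted p were 0.637 and 0.675.

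Neighbouring clones in the deposited table had related values. The average effect of o2 had a Spearman rho of 0.31 between clones 1 place apart and 0.027 between clones 200 apart, and the difference of the dye-swap arrays 0.44 and 0.0086.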
